A study of Arabidopsis thaliana with 6 samples.

How the data were processed

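Gene expression was measured in rosette leaves of Arabidopsis thaliana with Affymetrix ATH1 arrays, which carry 22810 probe sets, each a group of short probes for one transcript or a few similar ones. Per the labels' protocols, leaves 3 to 6 were taken from plants 3 weeks old that were grown at 20 °C with 20 h of light and 4 h of dark, total RNA was isolated with a QIAGEN RNeasy kit, and it was labelled with the Affymetrix 3' IVT Express kit, which primes from the poly(A) tail. There were 6 arrays, 3 of line A6 and 3 of wild type, and the labels call the replicates of each line biological. Each array was assigned to its line from its label.

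The values deposited by the authors, taken here as log2 values, were made with RMA, per the submitters' processing notes, which give neither version nor log base. RMA consists of background correction, quantile normalization and summary of probes into probe sets. The deposited values were also centred: the median of each probe set over the 6 arrays was 0 within 5.0e-07. Base 2 was assumed because RMA gives log2. The centring is not described in words, the log base stays unknown, and the direction is that of a 1-colour signal. Values ran from -3.74 to 7.13, and the array medians were -0.012, -0.013 and 0.007 in A6 replicates 1 to 3 and 0.022, -0.004 and 0.007 in wild-type replicates 1 to 3. Centring leaves differences between arrays as they were but removes the level of each probe set, so no probe set could be called present or absent, no signal over background could be given, and probe sets could not be filtered or ranked by brightness. The number of arrays limits the precision.

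Probe sets were named with the platform annotation paired with the series, updated through RefSeq gene names of assembly TAIR10.1, which served only for names and for which genes neighbour each other. Of the 22810 probe sets, 13513 paired with 1 gene, 503 with several genes, 8730 were not listed and are unnamed here, and 64 were control probe sets, which were kept out of the tests. RefSeq names matched 13436 of the 1-gene probe sets, and 1535 genes had a symbol other than the locus code. The 1-gene probe sets covered 13355 genes. The plan was to represent a gene with several probe sets by the brightest, which centred values do not allow. The plainest probe suffix and then the lowest probe number were used instead for those 147 genes. In 37 of them the probe sets differed in sign, and in 0 were they called in opposite directions. The probe set of MTA, the methyltransferase gene of line A6, is not analysed here by name.

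Differences between A6 and wild type were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the line as the only term, two-sided, over 22746 probe sets. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. A 2-fold limit means an absolute log2 difference of at least 1. All adjusted p-values of genes and probe sets given here are from limma, and a log2 difference is A6 minus wild type with its standard error (SE). Intervals are 95% intervals. The procedure was tested on simulated data for this comparison over 22746 probe sets: 75% of 100 probe sets changed by 1 log2 unit and 99% of 100 changed by 2 were recovered, with 4 unchanged ones called, and simulated data with no change gave 0 calls and 5.49% of unadjusted p-values under 0.05. Camera was run on the simulated data with no change after a shift was added to a list, and called that list and not an unshifted one. Genes were simulated independently of each other, so this run cannot show how camera performs on lists of correlated genes.

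Gene lists were fixed from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. The annotation held 81 of the 562 listed nuclear loci. A listed locus is called measured here only if the annotation names it, and others may lie among the unnamed probe sets. The 26 fixed lists include plastid-encoded and mitochondrion-encoded genes, taken as the genes that RefSeq places on those genomes. Lists with at least 3 measured members were tested with camera at a preset correlation between genes of 0.01, which left 17 fixed lists. Ribosomal protein lists were not analysed here because they needed gene descriptions. Because so few listed loci were measured, 20 more lists were drawn from symbol families after the annotation had been seen and before any difference was computed. They were adjusted as a separate family. Camera with an estimated correlation and fry were run beside camera.

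Genes are named by this rule. Among genes with adjusted p under 0.05 and no overlap between A6 and wild-type values, the 3 largest rises and 3 largest falls were taken whatever their name, and the 12 largest of each among genes with a symbol. From each fixed list up to 3 called members with the lowest adjusted p were taken, or, where none was called, up to 2 members as values. All measured genes of the m6A list were taken. Genes named outside this rule are marked as chosen after their values were seen.

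The alternatives planned before the data were examined were a replicate block, arrays centred on their medians, array weights, the mean 3' minus 5' difference of control probe sets as a covariate, each array left out in turn, only 1-gene probe sets, an ordinary equal-variance test in place of moderated variances, and for the lists other set tests, stricter name matching and gene means. Alternatives chosen after seeing the data were a robust prior, a block for the 2 arrays with high hybridisation spike-ins, and leaving both of those arrays out. Quantile normalization of the arrays, a filter on dim probe sets and an intensity trend were not run, because centred values hold no signal level.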

Results

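Transcript levels were compared between rosette leaves of 3 A6 samples and 3 wild-type samples, each hybridised to its own array. The series is described as a study of a plant deficient in N6-adenosine methylation. Line A6 is known as an mta mutant in which MTA, the catalytic subunit of the mRNA methyltransferase, is expressed from the embryo-active ABI3 promoter. The comparison asks which leaf transcripts differ in level between this line and wild type. These arrays do not measure methylation. Because A6 is the only mutant line, effects of low methylation cannot be told apart from other effects of the line. The level of MTA itself, which would check the labels, is not analysed here. All values are log2 units centred per probe set, so they give differences between arrays and not absolute levels.

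The largest rises among the genes with a name or locus code were those of CHI, AT5G55450 and AT2G43620. CHI (AT2G43570), annotated as a chitinase and not the chalcone isomerase of the same abbreviation, had a centred log2 value of 2.38 ± 0.81 (SD, n = 3) in A6 and -2.05 ± 0.55 (SD, n = 3) in wild type, a 21.6-fold rise. SBT3.3, a subtilase known from immune priming, rose by 3.53 log2 units (SE 0.17, adjusted p = 8.44e-05). WRKY53, a transcription factor of senescence and defence, rose 7.08-fold (log2 2.82, SE 0.20, adjusted p = 0.000479). AT5G55450 and AT2G43620 rose by 4.26 (SE 0.45) and 3.75 (SE 0.15) log2 units. All 5 genes kept their calls when any 1 array was left out (highest adjusted p = 0.0147). With the 3' minus 5' control difference as a covariate, a sign of RNA quality that also separated the lines, CHI had a log2 difference of 4.31 (adjusted p = 0.0568), and 25 of the 44 called genes named here no longer passed.

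Across all 22746 probe sets, 2222 differed between the lines (9.77%), of which 1143 were higher and 1079 lower in A6. Changes of at least 2-fold were less even: 455 probe sets rose and 126 fell, so that 78.3% of 581 were rises. At 4-fold the counts were 125 and 11, and at 8-fold 33 and 1. Among the 13355 genes, 577 rose and 578 fell, with 222 and 64 at 2-fold. Unnamed probe sets made up 225 of the 2-fold rises and 55 of the 2-fold falls, and both the largest rise (5.30 log2 units) and the largest fall (-3.87) were in unnamed probe sets. All 3 A6 values lay apart from all 3 wild-type values for 29% of probe sets, where chance gives 10%, and for each of the 2222 called ones. The count of 2222 was 766 without A6 replicate 1, 993 without A6 replicate 2, 1103 without wild-type replicate 2, 1222 without wild-type replicate 3 and 3484 without wild-type replicate 1, and it ranged from 229 with an ordinary equal-variance test to 4691 with array weights. Falls numbered 659 without A6 replicate 3, and 2-fold falls 208 without wild-type replicate 1. Under the 3' minus 5' covariate 146 probe sets rose and 144 fell, each by at least 2-fold, and the share of rises was 50.3%.

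**Figure D1:**
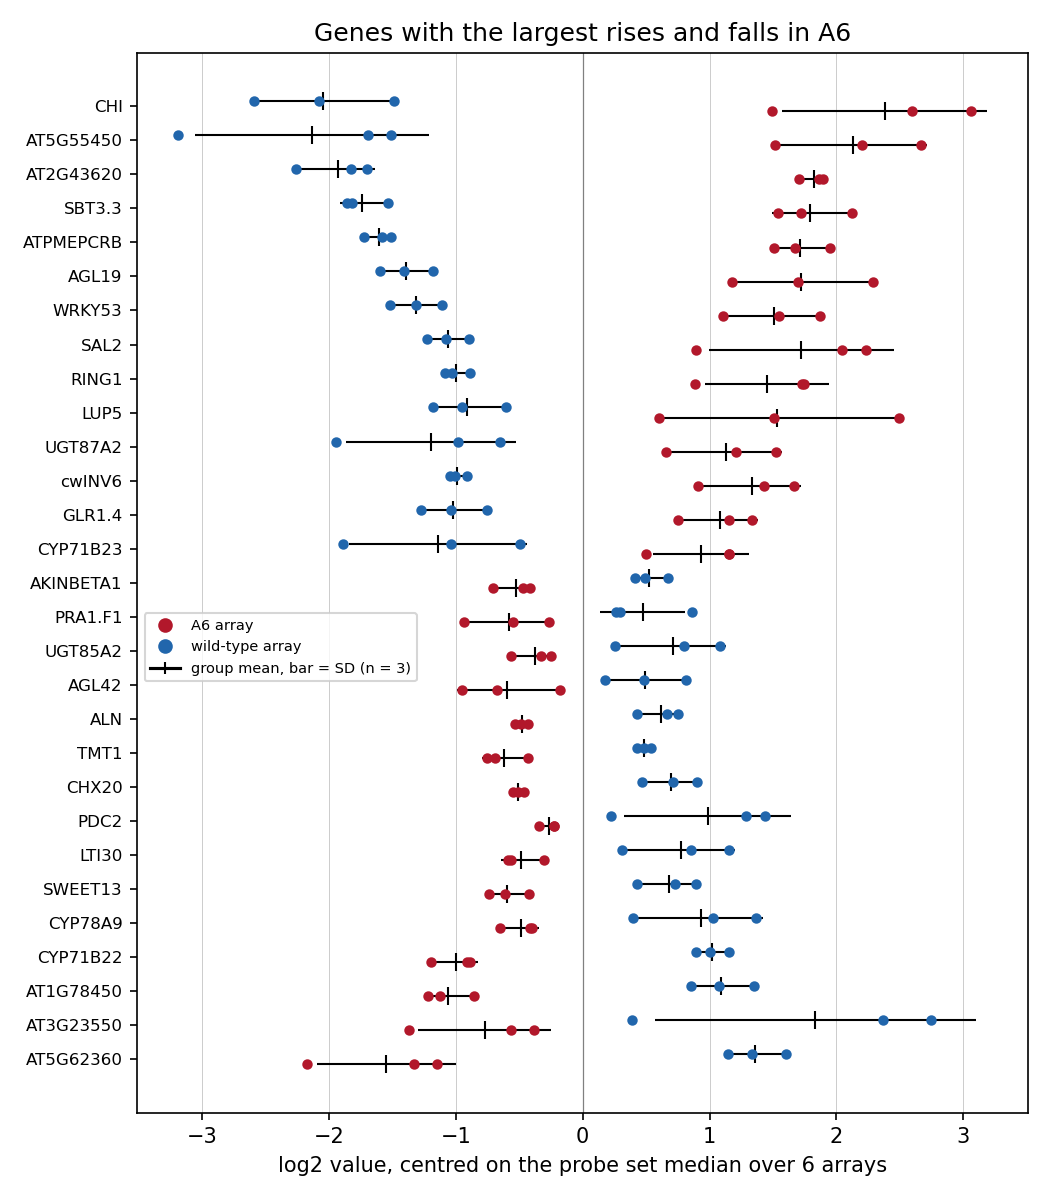
Centred log2 values (horizontal axis) of the genes with the largest rises and falls in A6 (vertical axis), with red points for A6 arrays, blue points for wild-type arrays, and black marks and bars for group means and SDs (n = 3). The genes drawn were chosen to have no overlap between A6 and wild-type points, and CHI shows the widest gap between means, 4.43 log2 units.

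Of the 12 largest rises among genes with a symbol, 9 more were these. ATPMEPCRB, a pectin methylesterase, rose by 3.32 log2 units (SE 0.13, adjusted p = 5.71e-05). AGL19, a MADS-box promoter of flowering, rose by 3.12 (SE 0.26). SAL2, of a family of inositol polyphosphate phosphatases, rose by 2.79 (SE 0.32), and RING1, a RING-type ubiquitin ligase, by 2.46 (SE 0.22). LUP5, an oxidosqualene cyclase of triterpene synthesis, rose by 2.45 (SE 0.41), and the glycosyltransferase UGT87A2 by 2.32 (SE 0.34). The fructan exohydrolase cwINV6 rose by 2.32 (SE 0.18), the glutamate receptor-like gene GLR1.4 by 2.101 (SE 0.19), and the cytochrome P450 CYP71B23 by 2.07 (SE 0.34). Without A6 replicate 1 the adjusted p of LUP5 was 0.0515 and that of CYP71B23 was 0.0511. The differences of CYP71B23 and UGT87A2 with the 3' minus 5' covariate were 0.86 (adjusted p = 0.351) and 1.39 (adjusted p = 0.236), and those of SAL2 and LUP5 were 3.26 (adjusted p = 0.0537) and 3.14 (adjusted p = 0.0949).

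The largest falls were smaller than the largest rises. AT5G62360 had a log2 difference of -2.91 (SE 0.26, adjusted p = 0.00103), AT3G23550 of -2.61 (SE 0.57, adjusted p = 0.0271) and AT1G78450 of -2.16 (SE 0.15). CYP71B22, which belongs to the same cytochrome P450 subfamily as the rising CYP71B23, had a difference of -2.01 (SE 0.12, adjusted p = 0.000325). CYP78A9, a cytochrome P450 known from fruit growth, fell by 1.42 (SE 0.23). The sucrose transporter SWEET13 fell by 1.28 (SE 0.15) and the tonoplast sugar transporter TMT1 by 1.11 (SE 0.12). The SnRK1 kinase subunit gene AKINBETA1 fell by 1.05 (SE 0.12). The pyruvate decarboxylase PDC2 fell by 1.25 (SE 0.29), the guard-cell cation exchanger CHX20 by 1.201 (SE 0.13), the allantoinase ALN by 1.097 (SE 0.11), UGT85A2 by 1.09 (SE 0.20) and PRA1.F1 by 1.05 (SE 0.21). AT3G23550 and PDC2 lost their calls without each array except wild-type replicate 1 (adjusted p 0.0684 to 0.0999 and 0.0919 to 0.114), UGT85A2 without any A6 array or without wild-type replicate 2 (0.0543 to 0.0655), and PRA1.F1 without A6 replicate 1 (0.0796), A6 replicate 3 (0.0579) or wild-type replicate 2 (0.0517). Fitted with the 3' minus 5' covariate, SWEET13, TMT1, AKINBETA1, UGT85A2 and PRA1.F1 had differences of -1.05, -1.23, -1.19, -1.67 and -0.46, with adjusted p-values of 0.11, 0.0521, 0.0607, 0.0599 and 0.533.

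All 3 measured members of the salicylate-linked defence list rose, 3 also when adjusted over the list alone. Beside WRKY53 these were GRX480, a glutaredoxin induced by salicylate (log2 difference 1.25, SE 0.17, adjusted p = 0.00448), and SAG101, a partner of EDS1 in immune signalling (0.71, SE 0.15, adjusted p = 0.0274). The list median was 1.25 and camera gave an adjusted p of 0.00011, which became adjusted p = 0.264 with an estimated correlation, and fry gave an adjusted p of 0.00737. Of 34 listed genes only these 3 were measured under a name. SAG101 lost its call without A6 replicate 1 (adjusted p = 0.116), A6 replicate 2 (0.101), wild-type replicate 2 (0.0616) or wild-type replicate 3 (0.0694), and with the 3' minus 5' covariate GRX480 and SAG101 had differences of 1.603 and 0.47 (adjusted p = 0.0567 and 0.441) while the list kept its call (camera adjusted p = 0.0128).

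Of 6 measured heat shock genes 2 rose (2 adjusted over the list alone) and 4 did not pass, and 6 of 6 had higher values in A6. ROF2 (AT5G48570), a heat-induced co-chaperone, rose by 0.80 (SE 0.14) and HSP23.5 (AT5G51440), a small heat shock protein, by 0.68 (SE 0.12). The list had a camera adjusted p of 0.0124, and adjusted p = 0.264 with an estimated correlation. Without A6 replicate 1 the adjusted p of ROF2 was 0.0629 and that of HSP23.5 was 0.0759, and without wild-type replicate 3 that of HSP23.5 was 0.0535. With the 3' minus 5' covariate the differences were 0.43 and 0.36 (adjusted p = 0.371 and 0.41) and the camera adjusted p was 0.311, and without both arrays with high spike-ins the latter was 0.0535.

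Of the 2 measured genes of endoplasmic reticulum protein folding, the co-chaperone ERDJ3B rose by 1.25 (SE 0.18, adjusted p = 0.0052) and the other did not pass over all probe sets, while 2 passed when adjusted over the list alone. ERDJ3B had a difference of 1.52 (adjusted p = 0.0731) with the 3' minus 5' covariate.

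Cold and abscisic acid responsive genes went both ways. COR15A and COR15B, which encode chloroplast proteins of freezing tolerance, rose by 1.99 (SE 0.22) and 1.12 (SE 0.23), and the dehydrin LTI30 fell by 1.26 (SE 0.21). Of 5 measured members 2 rose, 1 fell and 2 did not pass, with 2 rises and 1 fall adjusted over the list alone. The list median was -0.43 and its mean 0.15, so these differed in sign, and its camera adjusted p was 0.967. COR15B lost its call without A6 replicate 1 (adjusted p = 0.0515), A6 replicate 2 (0.057), A6 replicate 3 (0.0521) or wild-type replicate 2 (0.0558), and LTI30 without A6 replicate 1 (0.0528). Adding the 3' minus 5' covariate gave COR15B a difference of 1.55 with adjusted p = 0.113, and LTI30 a difference of -0.54 with adjusted p = 0.361.

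Both measured regulators of iron homeostasis fell. BHLH101, a transcription factor of the iron deficiency response, fell by 0.96 (SE 0.14, adjusted p = 0.00577) and PYE (POPEYE) by 0.93 (SE 0.16, adjusted p = 0.0126), with 2 falls also when adjusted over the list alone. Only 2 of 23 listed genes were measured under a name, so the list was not tested as a set. PYE had an adjusted p of 0.061 without A6 replicate 1, and BHLH101 had a difference of -0.56 (adjusted p = 0.234) with the 3' minus 5' covariate.

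**Figure D2:**
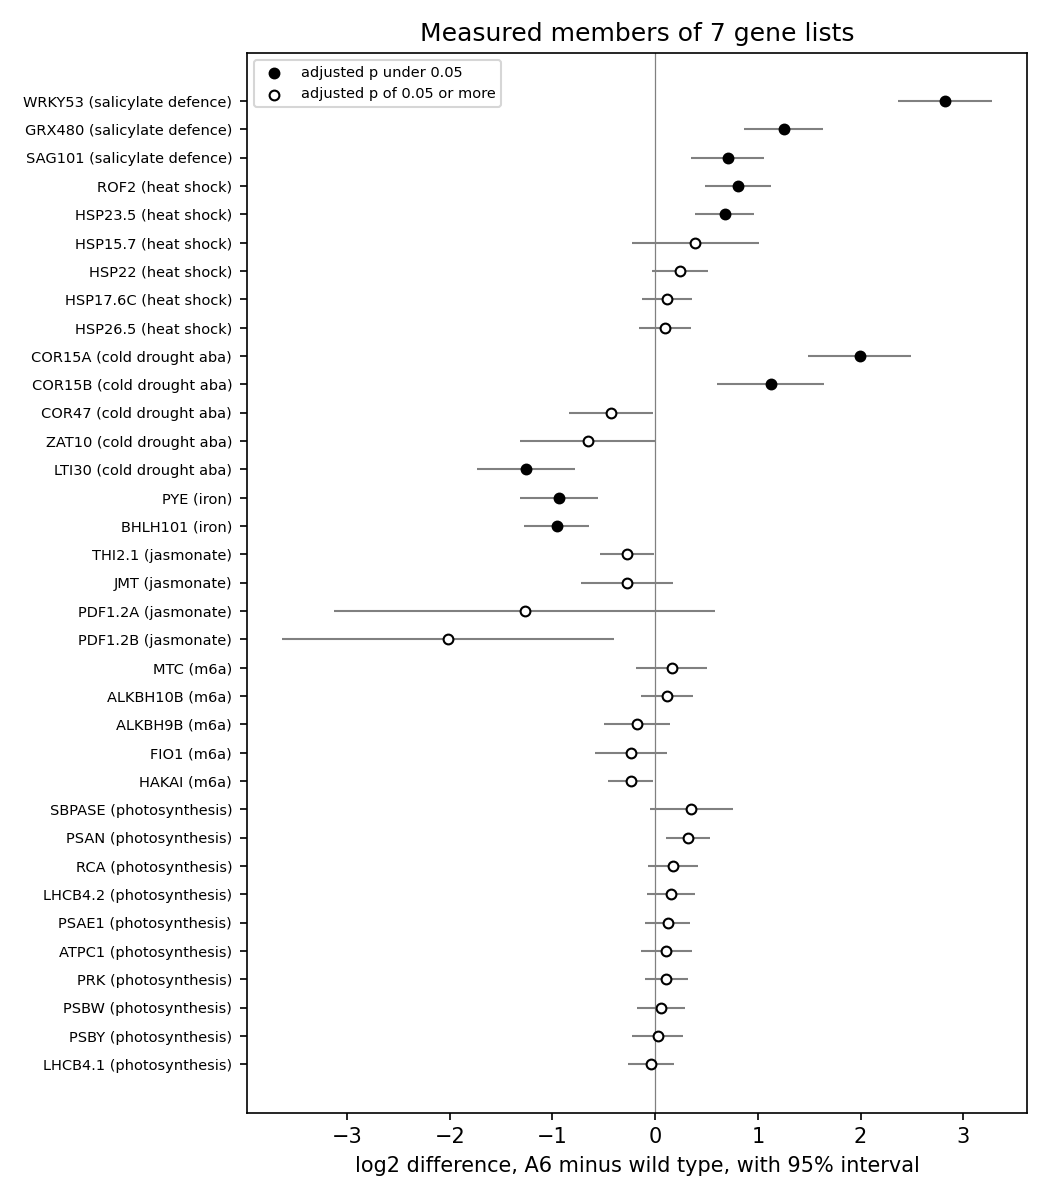
Log2 difference, A6 minus wild type (horizontal axis), of the measured members of 7 gene lists (vertical axis), with 95% intervals as bars, filled points for adjusted p under 0.05 over all probe sets and open points for the rest. All 3 members of the salicylate-linked list and both iron regulators are filled, and none of the 5 m6A genes is.

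Of 14 listed genes of the m6A machinery only 5 were measured under a name, and none of these passed the test. HAKAI (AT5G01160), a component of the writer complex, had a log2 difference of -0.24 (SE 0.10, adjusted p = 0.173) and FIO1, which methylates U6 RNA, of -0.24 (SE 0.15, adjusted p = 0.409). MTC (AT1G19340) had 0.16 (SE 0.15), the eraser ALKBH9B (AT2G17970) -0.18 (SE 0.14) and the eraser ALKBH10B (AT4G02940) 0.12 (SE 0.11). The 95% intervals of these 5 genes lay between -0.59 and 0.51. With limma 0 of 5 passed, also adjusted over the list alone, 1 had an unadjusted p under 0.05, and the camera adjusted p was 0.921. The differences of ALKBH9B and ALKBH10B had the opposite sign with the 3' minus 5' covariate, 0.22 and -0.11.

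Single members of several other lists changed. Among flowering genes, AGL42 fell by 1.09 (SE 0.23) and 4 of 5 did not pass, while adjusted over the list alone 3 rose and 2 fell; the camera adjusted p was 0.921, with a median of 0.28 and a mean of -0.05. AGL42 lost its call without A6 replicate 1 (adjusted p = 0.0862), A6 replicate 3 (0.07) or wild-type replicate 3 (0.0662), and had a difference of -0.46 (adjusted p = 0.558) with the 3' minus 5' covariate. The clock gene GI, one of 2 measured clock genes, fell by 0.56 (SE 0.10; 1 fall adjusted over the list alone), with adjusted p = 0.0733 without A6 replicate 1, and with a difference of -0.50 (adjusted p = 0.241) with the covariate. In the trichome list SIM, a cell cycle inhibitor that acts in trichome endoreduplication, fell by 0.55 (SE 0.11). Of that list 3 of 4 did not pass (1 rise and 1 fall adjusted over the list alone, camera adjusted p = 0.967). SIM lost its call without A6 replicate 1 (adjusted p = 0.0795), A6 replicate 2 (0.0784), wild-type replicate 2 (0.0755) or wild-type replicate 3 (0.0727), and with the covariate (a difference of -0.73, adjusted p = 0.128).

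In metabolism and hormone lists, the flavonoid glycosyltransferase UGT78D2 rose by 0.71 (SE 0.10), as 1 call among 7 flavonoid genes (2 adjusted over the list alone, camera adjusted p = 0.182). WES1 (GH3.5), which conjugates auxin and salicylate to amino acids, rose by 0.83 (SE 0.14), as 1 call among 6 auxin genes (1 adjusted over the list alone, camera adjusted p = 0.184). WES1 had adjusted p = 0.0599 without A6 replicate 1, and with the 3' minus 5' covariate UGT78D2 and WES1 had differences of 0.73 and 0.69 (adjusted p = 0.125 and 0.234).

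No member passed with limma in the remaining lists of nuclear genes. Of 10 photosynthesis genes 9 had higher values in A6, led by PSAN (0.32, SE 0.09, adjusted p = 0.0739) and SBPASE (0.35, SE 0.18, adjusted p = 0.269), and the camera adjusted p was 0.0842. All 4 jasmonate genes had lower values in A6: the defensin PDF1.2b had -2.02 with SD 0.95 in A6 and 1.41 in wild type (adjusted p = 0.12), THI2.1 had -0.28 (adjusted p = 0.184), and the camera adjusted p was 0.141. At an unadjusted p under 0.05 the counts were 1 and 2. Array weights gave limma adjusted p-values of 0.0323 for PSAN, 0.0334 for SBPASE and 0.00821 for PDF1.2b, so these passed. Without wild-type replicate 1 the camera adjusted p was 0.0437 for photosynthesis and 0.0424 for jasmonate (with an estimated correlation and all arrays, adjusted p = 0.681 and 0.601), SBPASE had a difference of 0.54 (adjusted p = 0.0238) and PDF1.2b of -2.75 (adjusted p = 0.0124), and without A6 replicate 2 the camera adjusted p of jasmonate was 0.0378.

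The glucosinolate genes UGT74B1 and BCAT4 had differences of -0.17 and 0.15, the cell cycle genes PRL (MCM7) and AUR1 of 0.52 and -0.14, and the nonsense-mediated decay genes UPF3 and UPF2 (AT2G39260) of -0.12 and -0.01. Camera gave an adjusted p of 0.967 for each of these 3 lists, and the cell cycle list had a median of -0.14 and a mean of 0.08. Without wild-type replicate 1 PRL had a difference of 0.92 (adjusted p = 0.00423) and BCAT4 of -0.03. The senescence genes SAG29 and WRKY6 had -0.26 and 0.25. In these 4 lists 0 genes had an unadjusted p under 0.05 with limma, and the counts adjusted over the list alone were 0 for them and for photosynthesis and jasmonate.

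In the fixed lists, no measured marker of other organs and cell types passed. Only 3 of 16 listed root, 3 of 12 stomatal, 1 of 20 phloem and xylem and 1 of 9 meristem markers were measured under a name. So few cannot show whether the makeup of the tissue differed. STOMAGEN, which rose, and the guard-cell gene CHX20, which fell, were not among these measured markers. EXPA7 and PYK10, of the root list, had -0.13 and -0.12 (camera adjusted p = 0.921), and MUTE and FMA (FAMA), of the stomatal lineage, had -0.15 and 0.15 (camera adjusted p = 0.967). The sugar transporter SWEET11, a phloem marker, had -0.23 and the meristem gene CLV3 had -0.20. With limma 0 of these lists' measured markers had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. PYK10 had 0.06 without wild-type replicate 3, and CLV3 had 0.08 without wild-type replicate 1. The fixed lists of seed markers, phosphate starvation and shoot branching genes were not analysed here.

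Organelle transcripts had medians near or below 0. Because the labelling primes from the poly(A) tail, their values may depend on tailing as well as on abundance, which was not tested. Among 69 plastid-encoded genes 25 had higher and 44 lower values in A6, with a median of -0.04, and ndhK, a subunit of the NDH complex, was the 1 called gene (-0.60, SE 0.15, adjusted p = 0.042; 0 adjusted over the list alone and 16 at an unadjusted p under 0.05 with limma). ndhK lost its call without any 1 of the 6 arrays, at adjusted p 0.054 to 0.131. Of 11 mitochondrion-encoded genes 9 had lower values in A6 with a median of -0.22, and nad9, of respiratory complex I, fell by 1.004 (SE 0.23, adjusted p = 0.0326; 1 fall adjusted over the list alone). nad9 lost its call without A6 replicate 1 (adjusted p = 0.12), A6 replicate 3 (0.0963), wild-type replicate 2 (0.115) or wild-type replicate 3 (0.104). Camera adjusted p-values were 0.921 and 0.0594, and the latter passed without A6 replicate 1 (0.0171), A6 replicate 2 (0.0298) or wild-type replicate 1 (0.0275), with the spike-in block (0.0326) and with the mean of all probe sets of a gene (0.0219), while with an estimated correlation it had adjusted p = 0.5. With the 3' minus 5' covariate ndhK and nad9 had differences of -0.34 and -1.62 (adjusted p = 0.565 and 0.0868).

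Signs of RNA and hybridisation quality were read from the control probe sets. The mean 3' minus 5' difference was -0.025 ± 0.007 (SD, n = 3) in A6 and 0.049 ± 0.038 (SD, n = 3) in wild type, with no overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Over the tested probe sets and not the controls, the interquartile range was 0.192 ± 0.018 (SD, n = 3) in A6 and 0.234 ± 0.028 (SD, n = 3) in wild type (exact permutation p = 0.1). It describes deviations from each probe set's median and not signal or RNA quality, and was largest on wild-type replicate 1 (0.265). Hybridisation spike-ins averaged 0.13 ± 0.25 (SD, n = 3) and -0.03 ± 0.39 (SD, n = 3), with an exact permutation p of 0.5, and were high on A6 replicate 3 (0.41) and wild-type replicate 1 (0.40). Poly(A) spike-ins differed by -0.019 (exact permutation p = 0.7). Wild-type replicate 1 had the largest spread about its group mean, an SD of 0.249 over probe sets against 0.115 to 0.183 for the other 5 arrays.

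**Figure D3:**
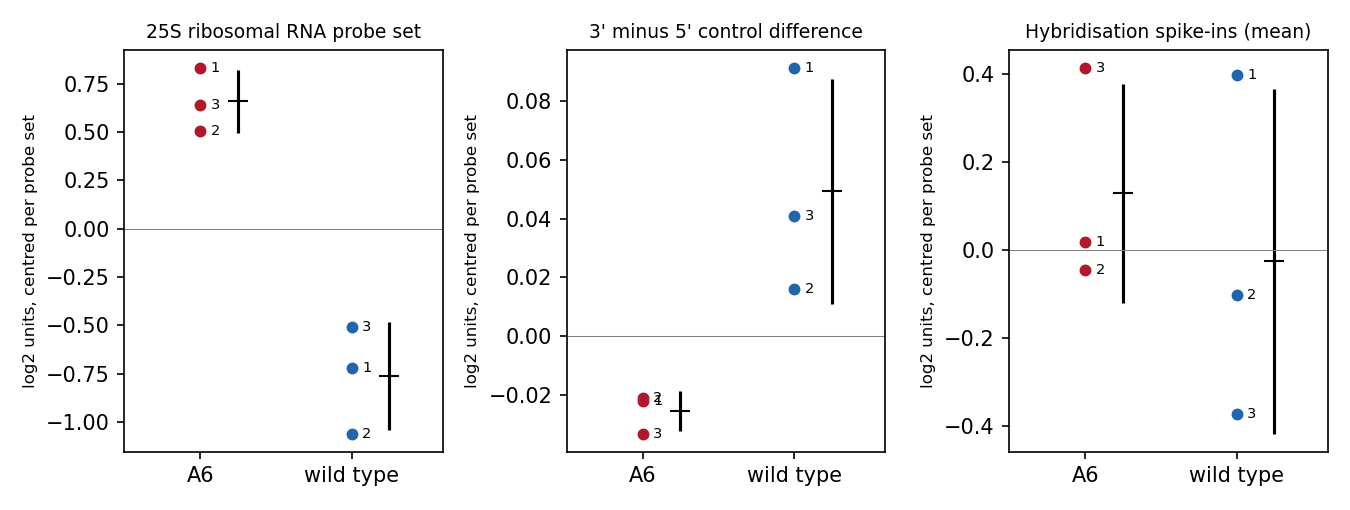
Control values per array in log2 units centred per probe set (vertical axes) for A6 and wild type (horizontal axes), with the 25S ribosomal RNA probe set on the left, the mean 3' minus 5' difference in the middle and the mean hybridisation spike-in on the right; points carry replicate numbers, and black marks and bars are group means and SDs (n = 3). A6 and wild type are apart in the left and middle panels and overlap on the right.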

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

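The fit without the arrays with high spike-ins, the spike-in level, the comparison with random covariates and the slopes of single arrays were tests chosen only after the results were seen.

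Control probe sets, which were not among the tested probe sets, differed between the lines. The 25S ribosomal RNA probe set was higher in A6 by 1.42 log2 units (adjusted p = 0.00445 over the 64 controls with limma), and GAPDH control probe sets by 0.565 (adjusted p = 0.046) and 0.576 (adjusted p = 0.0453), each with all 3 A6 arrays above all 3 wild-type arrays, while the 5S ribosomal RNA probe set had a difference of -0.251 (adjusted p = 0.235) with all 3 A6 arrays below. More RNA without a poly(A) tail in the labelled pool of A6 would raise plastid transcripts. Their median difference was -0.04 (95% interval over genes -0.099 to -0.01). With each array centred the median was -0.026 (-0.084 to 0.004), so that the interval then reached 0. Both intervals resample genes of the same 6 arrays, with an estimated correlation of 0.281, and leave out variation between arrays. Without A6 replicate 3 the camera direction of plastid genes was upward, not past the threshold. The sign of the plastid difference is therefore not settled, and a small rise stays open. Both medians lie far below 1.42, which argues against a rise of plastid transcripts as large as that of the 25S probe set. Mitochondrion-encoded genes, not part of that prediction, had a median of -0.221 (-0.294 to -0.078 over genes of the same arrays), and 9 of 11 were lower. They showed no rise either, but their fall did not pass with camera (adjusted p = 0.0594). The hybridisation spike-ins differed by 0.155, with SDs of 0.249 in A6 and 0.392 in wild type, so they did not share the 25S difference. They cannot decide on a higher scanner level, because the quantile normalization of RMA largely removes a level common to a whole array. A biological difference in ribosomal RNA stays open and was not tested.

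Rises of at least 2-fold outnumbered falls in A6, 455 against 126, and 79.2% of 2-fold calls were rises with each array centred and 72.6% without the 2 arrays with high spike-ins. Neither share decides. Array medians already lay from -0.013 to 0.022, so centring could move little and array scaling stays open. The 2 arrays with high spike-ins are 1 of each line. A shift that both share cancels from the difference between the lines, which argues against it as the source of the excess. With a block for these 2 arrays 489 probe sets rose and 131 fell at 2-fold (78.9% rises). A hybridisation effect that differed between the 2 arrays stays open. RNA degradation stays open too. With the 3' minus 5' covariate 146 probe sets rose and 144 fell at 2-fold, so 50.3% were rises and these calls showed no excess. Of these 290 calls 171 were among the 581, so 29.4% of the 581 remained. Under 50% had been set beforehand as what degradation would give. However, the covariate overlaps with the line (variance inflation 3.87). With the same overlap, 100 random covariates, added after that outcome, left a median of 4.39% (0 to 67.3%), fewer than 29.4% in 76 cases. They were compared by the calls that remained and not by the share of rises. The 581 differences kept their sign, with a median size of 1.38 before and 1.49 after and a median SE of 0.201 and 0.347. Of the 410 that ended 299 were still at least 2-fold and 111 were not. Wider errors and, for some, smaller differences thus ended them. Within the lines the covariate varied most through wild-type replicate 1 (0.091, against 0.016 and 0.041 on wild-type replicates 2 and 3). Without that array 573 of the 581 still passed the threshold, and 71.6% of 2-fold calls were rises. The other wild-type arrays still lay above all A6 arrays (-0.033 to -0.021) in this measure, so degradation and line cannot be told apart. Of the 10 splits of the 6 arrays 1, the real one, gave as many 2-fold calls (581, highest other 0), and 10 splits are too few for a share under 0.05.

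Rises were smaller in A6 replicate 3 than in A6 replicates 1 and 2. For the 487 probe sets that rose at least 2-fold without replicate 3 its slope on the other A6 arrays was 0.726, and for the 135 that fell it was 0.888. An even compression of that array would give like slopes, and the difference was -0.162, but the same difference ran from -0.133 to 0.384 in the other 5 arrays, and choosing probe sets on the other replicates moves each slope by an unknown amount. Compression of the array therefore stays open, as does a biological difference between these plants, which was not tested.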

How the results depend on the processing

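The spike-in block, the fit without both arrays with high spike-ins and the robust prior were tests chosen only after the data were seen, and the symbol families after the annotation but before any difference was computed. Over 67 named genes and 871 alternative values, 763 kept direction and side of the threshold, 82 lost and 12 gained the call, and 14 changed sign, none of them (0) a called gene. Of 44 called genes 26 kept the call without any 1 array and 19 with the 3' minus 5' covariate, and none of the 581 2-fold calls changed sign in a fit. Counts of all calls, rises and falls were 4691, 2117 and 2574 with array weights, 3478, 1766 and 1712 with the spike-in block, 229, 97 and 132 with the ordinary equal-variance test, and 1166, 577 and 589 over probe sets with 1 gene, where fewer were tested. At 2-fold the last pair gave 87, 63 and 24, and 290, 223 and 67. With the 3' minus 5' covariate 290 were called, 146 up and 144 down, all at 2-fold, with 1 fixed list and 5 symbol families past the threshold. Without A6 replicate 3 and wild-type replicate 1 there were 3465 calls, 1803 falls, 219 2-fold falls and 1 fixed list. Leaving out 1 array gave 766 to 3484 calls, 465 to 1599 rises, 301 to 1885 falls, 91 to 208 2-fold falls, 2 to 5 fixed lists and 0 to 2 families. Camera with an estimated correlation called 0 fixed lists (2 at an unadjusted p under 0.05) and 0 families (0 unadjusted), fry called 2 lists and 0 families (2 unadjusted), and matching by borne-out names left 1 fixed list. The spike-in block and gene means each gave 3 fixed lists; the block holds 1 array of each line, so it moves errors and not differences.

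Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.129, 0.184 and -0.162. A6 replicate 1 correlated best with wild-type replicate 2 (0.16). A6 replicate 3 did so with wild-type replicate 1 (0.304), the highest of these correlations. That last pair are the arrays with high spike-ins, and the main fit held no term for a shift that they share. With the replicate block 1526 probe sets were called, 648 of them falls, with 1446 shared with the 2222; AGL42 (adjusted p = 0.0624), PRA1.F1 (0.0565), SAG101 (0.0545) and SIM (0.0509) lost their calls, and no other named gene or list call changed.

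Sign changes were UPF2 (AT2G39260) at 0.001 with arrays centred and -0.027 to 0.006 without 1 array, EXPA7 at 0.004 with array weights and 0.087 with the covariate, and with the covariate BCAT4 at -0.32, AUR1 at 0.078, MUTE at 0.044, CLV3 at 0.605, AT2G17970 at 0.222 and AT4G02940 at -0.113. Without 1 array BCAT4 ranged from -0.026 to 0.283, CLV3 from -0.353 to 0.085 and PYK10 from -0.218 to 0.062. Where no cause is given, the cause was not tested. Quantile normalization, a dim filter, an intensity trend, a robust prior for lists and the MTA level were not run, and signal over background is not known from centred values.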

Other observations

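Symbol families outside the fixed lists held more called genes; the families were chosen before any difference was computed, the genes named after their values were seen, and no test in this part was chosen only after its result was seen. Expansins and xyloglucan endotransglucosylases, which loosen cell walls, had 4 rises among 28 genes: EXLB1 (1.73, SE 0.12), XTH32 (1.21), XTH16 (0.88) and EXPA4 (0.76) (camera adjusted p = 0.0404, and adjusted p = 0.944 with an estimated correlation). Of the 10 autophagy conjugation genes 0 were called with limma (5 at an unadjusted p under 0.05) and 9 had lower values in A6, with 5 falls when adjusted over the list alone (camera adjusted p = 0.0404, and adjusted p = 0.944 with an estimated correlation). Both list calls were lost without A6 replicate 3 (0.199 and 0.302), wild-type replicate 2 (0.215 and 0.215) or wild-type replicate 3 (0.0533 and 0.188). The list of late embryogenesis abundant and cold-regulated genes split into 3 rises, which included DI21 (1.78, SE 0.13), and 3 falls. The falls included COR27 (-0.63) and XERICO (-0.70), a RING-type protein that was counted in the list although it is of neither kind. CYP71B genes had 3 rises, among them CYP71B36 (1.44, SE 0.15), and 2 falls. STOMAGEN, a peptide that promotes stomata, rose by 1.47 (SE 0.36, adjusted p = 0.0427), with an SD of 0.84 in wild type.

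Counts of rises and falls were 4 and 3 of 49 UDP-glycosyltransferases, 2 and 0 of 14 glutathione transferases, 1 and 2 of 14 SWEET transporters, 1 and 2 of 21 beta-glucosidases (BGLU25 rose by 1.86, SE 0.19), 1 and 0 of 7 calmodulin-like genes, 1 and 2 of 29 carboxypeptidase-like genes, 0 and 1 of 9 U-box ligases, 2 and 0 of 15 defensins and related genes (LCR69 rose by 1.87, SE 0.20), 1 and 1 of 40 AGAMOUS-like genes, and 0 and 3 of 24 ubiquitin conjugases and proteases. With limma 0 of 22 TBL, 7 tubulin, 10 RALF, 16 reproductive and 7 late seed marker genes were called (6, 2, 2, 2 and 0 at an unadjusted p under 0.05). Camera adjusted p-values of these 18 families, with the cold-regulated, CYP71B and stomatal ones, were 0.614 to 0.929. Under the 3' minus 5' covariate 3 of them passed upward: the cold-regulated (0.0275), carboxypeptidase-like (0.0275) and late seed (0.0194) families, each at adjusted p = 0.944 with an estimated correlation and no covariate. The cold-regulated and late seed families had downward camera directions, not past the threshold, without the covariate.

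A hypothesis tested was that called genes cluster on chromosomes. Neighbouring measured genes called in the same direction made 71 pairs, against a mean of 49.6 and a 95% range of 37 to 63 in 10000 shuffles, of which 20 gave as many and the highest gave 75. That lies above the range for chance order but not above the highest shuffle, the bound set beforehand for excluding it. A segment of another genome around the MTA locus was a candidate source: 11% of the 100 measured genes around MTA were called against a median of 9% over windows of that length, and 69.3% of windows had a lower share, which leaves the question open. Tandem copies that share probes were not tested.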
